A study of Rattus norvegicus with 7 samples.

How the data were processed

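Total RNA from 7 rat placenta samples was measured on an Affymetrix whole-genome rat expression array, 1 array per sample. Per the labels' protocols, 5 ug of total RNA was made into biotin-labelled complementary RNA and hybridised. The deposited values are linear MAS5 signal, an intensity per probe set, and MAS5 is named in the submitters' processing notes without a version. In each deposited column the mean with the lowest and highest 2% of values left out was 500 within rounding, so the columns had been scaled to a shared level, and the scaling target and any filter are not given in the sources used here. Detection calls were not used here. The number of arrays limits the precision, with 3 control and 4 ethanol arrays. No source used here says whether each array held 1 placenta or a pool, or how many dams contributed, so p-values measure only the spread between these samples, which may be technical. No arrays held identical values: the correlation of log2 signal between arrays was between 0.9302 and 0.9754.

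Of 31099 probe sets, 57 are array controls and were left out. The platform annotation gave 1 gene for 20826 probe sets, several for 436 and none for 9780, and no gene was named from a probe set with several. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCr8, which held 20758 of them under the current symbol and lacked 68. Coordinates are not given, since the array files name no genome build. Signals were taken to log2 with no pseudocount and no further normalisation, and the 40% of probe sets with the lowest mean were left out, which left 18625 probe sets. For gene-level tests the brightest probe set stood for its gene, which gave 10603 genes.

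Ethanol and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend). The number that opens the sample titles splits the arrays into 2 sets, each with both groups, and this title set was a block in the model. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are ethanol over control. A total of 38 gene lists with 753 entries, covering placental cell types, hormones, stress responses, metabolism and markers of other tissues a sample could hold, was written before the data were examined, and so were the samples, tests and alternatives. The 36 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 36. Camera with an estimated correlation and fry were alternatives. A list score is the mean over its genes of log2 signal minus the gene's mean over all arrays. Array measures were compared by exact two-sided permutation over the 35 splits of 7 arrays, for which the smallest possible p is 0.029.

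The genes named in the text followed a fixed rule: the 12 largest rises and 12 largest falls among genes past the threshold, filled by the smallest unadjusted p among genes with a log2 fold change of at least 0.58 in size and no overlap of the groups, plus up to 4 members with the smallest p from each list and every measured gene of the ethanol metabolism list. Symbols that are only locus numbers were passed over. The fill supplied all of these genes except Add3. Nckap5l and the unnamed probe sets were named outside the rule, after their values were seen.

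The alternatives were quantile normalization, scaling to the 75th percentile or the median, a pseudocount of 7.23 (the 10th percentile of all signals) or a floor at the 20th percentile, no filter or a 60% filter, no title set block, each title set alone, no variance trend, array weights, leaving out each array, other summaries of several probe sets, and other list tests. A covariate for the decidual list score was added after seeing the data. The scripts were tested on simulated data with 200 changed rows. At a log2 change of 1 the probe set comparison recovered 48% of changed rows and at 2 it recovered 85%, and 5.0% of its calls were false. For genes these shares were 71% and 93%, with 2.96% false. Both shifted lists were called, and 1 of 34 unshifted lists was. The simulated rows varied independently of each other, with no title set effect. These shares of false calls therefore may not hold for real genes, which vary together. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and plots.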

Results

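Placentas of Long-Evans rats were compared after voluntary drinking through gestation. Dams had access for 4 hours a day to 5% ethanol in 0.066% saccharin or to saccharin alone, and drank a mean of 16 ml. The labels give a mean peak maternal serum ethanol of 84 mg/dL. Placentas were taken on gestational day 20 after perfusion with saline. The comparison asks which placental transcripts differ after moderate ethanol exposure. There were 3 control and 4 ethanol arrays, and their median signal was between 109.9 and 126.5. The first principal component held 45.5% of the variance, and its scores were -33.6 ± 6.2 (SD, n = 3) in control and 25.2 ± 24.5 (SD, n = 4) in ethanol arrays (two-sided exact permutation p = 0.0571, adjusted 0.133 over 7 array measures). Ethanol replicate 4, at -3.63, lay nearest to the controls on this component. The difference between 3' and 5' probe sets, a sign of RNA or labelling quality, was largest in this array for Actb, with 2.23 log2 units, and for Gapdh, with 0.86, against 1.03 to 1.60 and 0.29 to 0.56 in the other arrays. For hexokinase, the other gene with such probe sets, it was largest in control replicate 1, with 2.11, and was 1.69 in ethanol replicate 4. The difference between the groups did not pass for Actb or Gapdh (two-sided exact permutation p = 0.971 and 0.714). For hexokinase it was 1.84 ± 0.24 (SD, n = 3) in control and 1.61 ± 0.06 (SD, n = 4) in ethanol arrays and did not pass either (two-sided exact permutation p = 0.0571, adjusted 0.133). The median signal was 123 ± 3.4 (SD, n = 3) in control and 112 ± 1.6 (SD, n = 4) in ethanol arrays (two-sided exact permutation p = 0.0286, adjusted 0.133).

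At single-gene level Add3, the gamma subunit of the membrane skeleton protein adducin, fell in ethanol placentas. Its log2 signal was 10.96 ± 0.07 (SD, n = 3) in control and 9.64 ± 0.16 (SD, n = 4) in ethanol placentas, a log2 fold change of -1.32 (SE 0.12, limma adjusted p = 0.0394). A further Add3 probe set gave -1.34 (SE 0.16). Add3 was the 1 gene of 10603 past the threshold. Among 18625 probe sets, 11 passed, 3 higher and 8 lower. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 1.73 (SE 0.21) on the log2 scale, and Gpr137b rose by 1.18 (SE 0.14). A probe set of Nckap5l rose by 2.78 (SE 0.29), from control signals of 28.1 to 52.1, near the 20th percentile of all signals, 21.5. This probe set was not the brightest of its gene, so it did not stand for Nckap5l at gene level. Hyou1, a chaperone of the endoplasmic reticulum, fell by 1.31 (SE 0.16), Scgb1a1, a secretoglobin, fell by 1.86 (SE 0.23) and the G protein subunit gene Gng8 fell by 3.11 (SE 0.39). The lowest Gng8 signal, 18.7 in ethanol replicate 3, lies under the 20th percentile of all signals, 21.5, so the size of this fold is uncertain, and it was -2.84 with a pseudocount added and between -3.40 and -1.92 over all alternatives. The rest were the other Add3 probe set and 3 probe sets without a gene name. These limma adjusted p-values were all 0.0474. The groups did not overlap for 18.5% of probe sets, against 5.71% by chance, and 3888 had an unadjusted p under 0.05, against 931 expected. These expected values are averages over possible splits. Genes vary together, so any single split can lie far from them. Neither quantity was counted over the splits, so the excess is no test of an ethanol effect. Without the title set block 231 probe sets (85 higher, 146 lower) and 243 genes (98 higher, 145 lower) passed. For the title set itself 0 probe sets and 0 genes passed in the limma fit. An unadjusted p under 0.05 was found for 1217 probe sets, against 931 expected, and for 638 genes, against 530 expected. This does not show that the sets are alike. Title set 1 alone, with 1 control and 2 ethanol arrays, so that the lone control was assumed to vary like the ethanol arrays, gave 3 probe sets, none of them among the 11. Title set 2 alone, with 2 arrays of each group, gave 0, where 1588 had an unadjusted p under 0.05. Leaving out ethanol replicate 4 gave 1138 probe sets and 857 genes, while control replicate 1, control replicate 2 or ethanol replicate 3 left out gave 0 of either, control replicate 3 left out gave 1 probe set and 0 genes, ethanol replicate 1 left out gave 2 and 3, and ethanol replicate 2 left out gave 15 and 6. Scaling arrays to their medians, which shifted the median log2 fold change by 0.136, gave 637 probe sets, of which 513 were higher, and quantile normalization gave 2, of which 1 was higher.

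Of the 24 genes named by rule, all but Add3 had an adjusted p of 0.0612 at gene level and so did not pass. The values on the higher side spanned 1.51-fold to 3.31-fold. They included Bmp4, a bone morphogenetic protein, with a log2 fold change of 1.07 (SE 0.16), the ganglioside enzyme gene St3gal5 with 0.93 (SE 0.13), the repulsive guidance gene Rgma with 1.03 (SE 0.15) and the kinase gene Ripk4 with 1.34 (SE 0.19). The others were Tp53bp2 (1.09), Epb41l4a (0.85), Prkch (0.79), Reps1 (0.66), Schip1 (0.64) and Slc45a4 (0.60). On the lower side, Grem1, a secreted antagonist of bone morphogenetic proteins, had a log2 fold change of -4.76 (SE 0.69). Its signal was between 445 and 1088 in control and between 12.5 and 103 in ethanol placentas, and 14.3 and 12.5 lie under the same percentile. The size of this fold is uncertain too. With the pseudocount added it was -4.34, and over all alternatives that measured it, it lay between -5.31 and -2.65. The alpha globin gene Hba-a3 had -2.74 (SE 0.39), the guanine deaminase gene Gda had -2.18 (SE 0.29) and Mlana had -2.15 (SE 0.30). Over the alternatives Hba-a3 lay between -3.97 and -2.20, Gda between -2.40 and -1.32 and Mlana between -2.42 and -1.65. Alas2 (-1.97), the macrophage lectin gene Clec10a (-1.62), Gnptab (-1.30) and Glrx (-1.02) were lower as well. Without the title set block, all 24 genes had an adjusted p between 0.00726 and 0.0478.

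**Figure D1:**
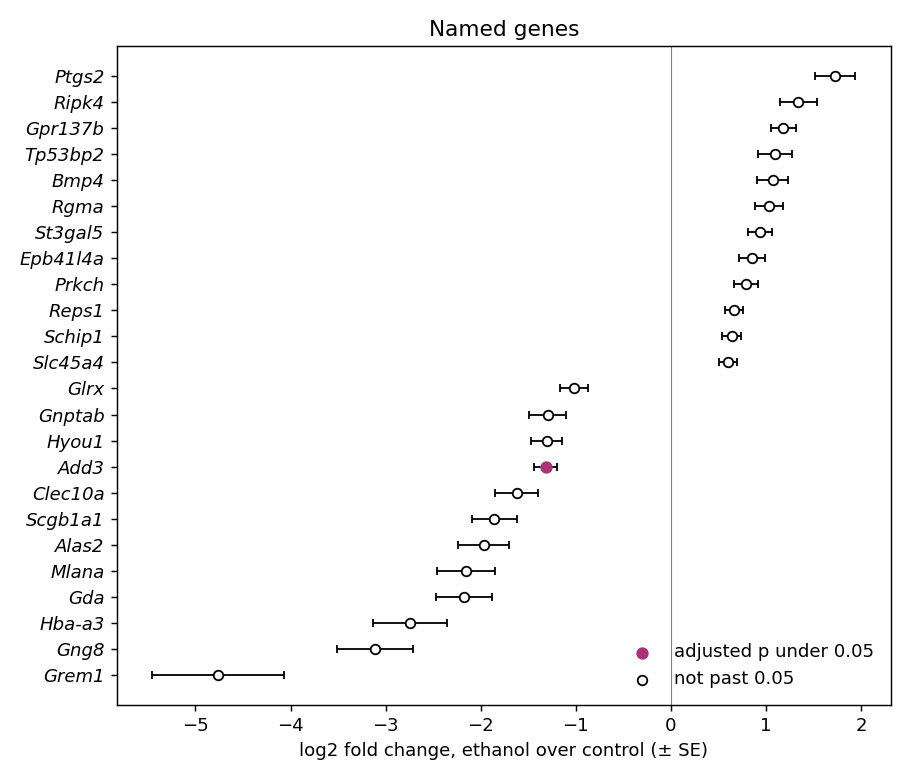
Log2 fold change of the 24 named genes, ethanol over control, on the horizontal axis, with bars for the standard error of the limma fit (3 control and 4 ethanol arrays). The filled point is Add3 at -1.32, past an adjusted p of 0.05, and the open points, from Grem1 at -4.76 to Ptgs2 at 1.73, were not past it at gene level.

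Of the 36 gene lists tested, 7 shifted as groups by camera at the preset correlation, 5 lower and 2 higher in ethanol placentas. With an estimated correlation 0 lists passed, and the 7 had camera adjusted p-values of 0.78 to 0.807. The estimates for the 7 lay between 0.154 for labyrinth markers and 0.9 for ribosomal proteins, against the preset 0.01. With fry 0 passed, with adjusted p-values of 0.195 to 0.53 for the 7. Red cell genes had the lowest median log2 fold change, -1.87, with 7 of 8 measured members lower (camera adjusted p = 0.00167). Adjusted over the list alone, 5 members passed, among them Alas2, which makes the first enzyme of haem synthesis in red cells, the embryonic globin gene Hbe1 (-2.97, SE 0.48), the beta globin gene Hbb (-2.26, SE 0.45) and the haemoglobin chaperone gene Ahsp (-1.95, SE 0.39). With 1 array left out Hbe1 lay between -3.67 (without control replicate 1) and -2.51 (without ethanol replicate 4), and Ahsp between -2.35 (without control replicate 2) and -1.33 (without control replicate 1). None of the 5 passed over all genes. Decidual markers, which mark the maternal layer of the placenta, had a median of -1.36 with 9 of 11 lower (camera adjusted p = 0.00525). Adjusted over the list alone 6 passed and over all genes 0, including the uterine homeobox genes Hoxa11 (-2.07, SE 0.40) and Hoxa10 (-1.61, SE 0.45), Hand2 (-1.36, SE 0.30) and the matrix proteoglycan gene Dcn (-2.42, SE 0.68). Dcn had signals of 513 and 455 in ethanol replicates 2 and 3 against 2305 and 3157 in ethanol replicates 1 and 4, and lay between -3.15 (without ethanol replicate 4) and -1.76 (without ethanol replicate 3) with 1 array left out. Decidual scores were 0.73 ± 0.19 (SD, n = 3) in control and -0.55 ± 0.72 (SD, n = 4) in ethanol placentas. The red cell scores were 0.77 ± 0.40 (SD, n = 3) and -0.58 ± 0.53 (SD, n = 4). Both calls held when any 1 array was left out. The decidual scores of ethanol replicates 2 and 3, -1.15 and -1.19, lay far under those of replicates 1 and 4, 0.052 and 0.098. All of these were under the lowest control, 0.548. Each title set and each fit with 1 array left out keeps at least 1 of the low pair. These alternatives thus cannot show whether that pair carries the shift.

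Prolactin family hormones were lower in 15 of 18 members with a median of -0.32 (camera adjusted p = 0.0143), and no member passed over the list alone or over all genes. With quantile normalization the median was -0.05 and the call was lost (adjusted p = 0.287). It was also lost without control replicate 3 (median -0.22, adjusted p = 0.0959) or ethanol replicate 3 (median -0.22, adjusted p = 0.0868). Several members are very bright, and Prl8a9, at 59993, was the highest signal of control replicate 3. The 100 brightest probe sets held 13.1 ± 1.8% (SD, n = 3) of the signal in control and 11.1 ± 1.5% (SD, n = 4) in ethanol arrays. This difference did not pass (two-sided exact permutation p = 0.143, adjusted 0.25). The lowest p-values of the prolactin list belonged to Prl3c1 (-1.17, SE 0.34), Prl3a1 (-0.70, SE 0.26) and Prl7a4 (-0.44, SE 0.17). Its member Prl8a2 (-0.35, SE 0.17) is on the decidual list as well. The prolactin shift is therefore not fully separate from the decidual one, and trophoblast and decidual sources were not told apart. Genes of endoplasmic reticulum stress were lower in 13 of 18 members with a median of -0.22 (camera adjusted p = 0.0326). Adjusted over the list alone 6 were lower and 1 was higher, and over all genes 0 passed. The lower ones included Hyou1 and the chaperone genes Pdia4 (-0.57, SE 0.10), Hsp90b1 (-0.57, SE 0.11) and Creld2 (-0.54, SE 0.12), while the stress transcription factor gene Atf3 was higher (0.75, SE 0.19). The call of this list held without control replicate 2 or ethanol replicate 4 and was lost without each of the other 5 arrays, with a median of -0.10 (adjusted p = 0.293) without control replicate 1. That array is the lone control of title set 1, so without it the contrast rests on title set 2, and title set 2 alone gave the same median (camera adjusted p = 0.359). Title set 1 alone gave a median of -0.47. The median was -0.11 with quantile normalization and -0.08 with median scaling, both with the call kept. Without the variance trend the call was lost (adjusted p = 0.0548), and the median was -0.37 without ethanol replicate 4 and -0.35 without control replicate 2. Ribosomal protein genes were lower in 17 of 17 members by a median of -0.19 (camera adjusted p = 0.0222), with none past the list alone or all genes. Their estimated correlation was 0.9, so the 17 members varied together and are not separate support. Their median turned to 0.04 with quantile normalization (camera adjusted p = 0.597). The call was also lost with median scaling (median -0.05, adjusted p = 0.0582), in title set 2 alone (adjusted p = 0.0814) and without control replicate 3 (median -0.06, adjusted p = 0.334), ethanol replicate 2 (adjusted p = 0.063) or ethanol replicate 3 (adjusted p = 0.135), and the median was -0.31 without control replicate 2. Labyrinth and syncytiotrophoblast markers, from the exchange layer, were higher in 11 of 13 with a median of 0.21 (camera adjusted p = 0.0326). The leptin receptor gene Lepr (1.01, SE 0.18) and Tead4 (0.42, SE 0.12) passed over the list alone and 0 passed over all genes. The call was lost without control replicate 3 (adjusted p = 0.178), ethanol replicate 2 (adjusted p = 0.063) or ethanol replicate 4 (adjusted p = 0.0628). It was also lost with the 60% filter (adjusted p = 0.0593), in title set 2 alone (adjusted p = 0.0518), without the variance trend (adjusted p = 0.0548) and with array weights (median 0.14, adjusted p = 0.0575). The median was 0.38 with quantile normalization, 0.39 without control replicate 2 and 0.35 without control replicate 1. Endothelial markers were higher in 11 of 12 with a median of 0.41 (camera adjusted p = 0.0161), with Vwf at 1.17 (SE 0.33), Tek at 0.74 (SE 0.27) and none past the list alone or all genes. Without control replicate 3 their median was 0.24 (adjusted p = 0.178) and without ethanol replicate 3 it was 0.32 (adjusted p = 0.0868), so that the call was lost. The score of ethanol replicate 4 lay within the range of the controls for the prolactin list (0.179, controls 0.026 to 0.368), endoplasmic reticulum stress (0.163, controls -0.037 to 0.23), ribosomal proteins (0.105, controls -0.052 to 0.399) and endothelial markers (-0.18, controls -0.495 to -0.037), while the other 3 ethanol arrays lay outside it. For labyrinth markers ethanol replicate 1, at -0.0037, lay under control replicate 2, at 0.048. Leaving out control replicate 3 gave 2 lists, leaving out ethanol replicate 3 gave 3 and leaving out control replicate 1 gave 11.

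**Figure D2:**
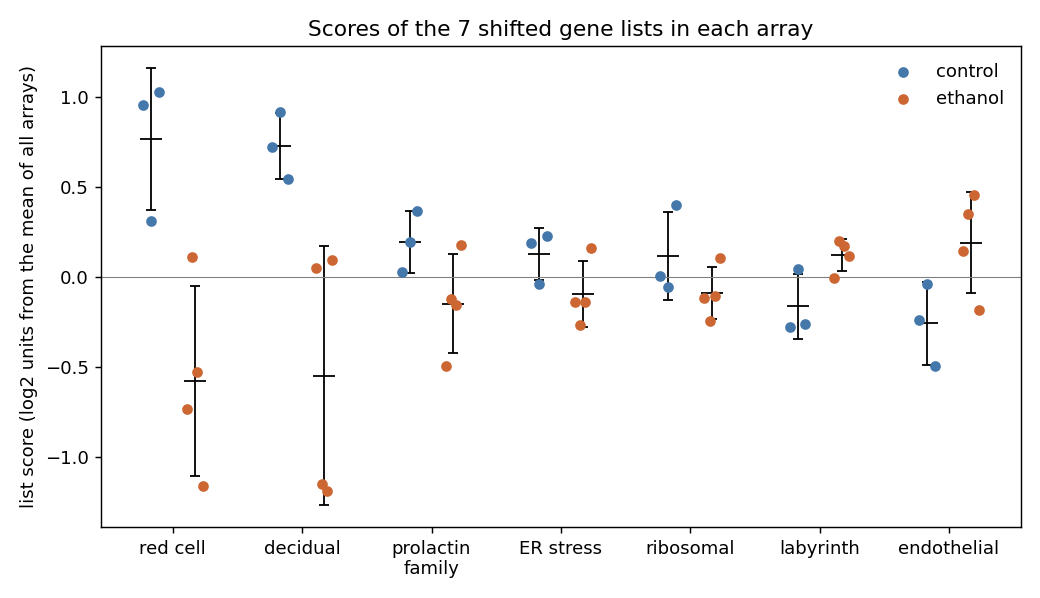
List score in log2 units for each array, with points for the 3 control and 4 ethanol arrays, and black bars for mean and SD. Decidual scores lie between 0.548 and 0.917 in control arrays and between -1.19 and 0.098 in ethanol arrays, and the 5 lower and 2 higher lists are those past a camera adjusted p of 0.05.

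Ethanol and aldehyde metabolism genes did not shift as a list (camera adjusted p = 0.295). Of the 8 measured, 1 passed over the list alone and 0 over all genes. The class I alcohol dehydrogenase gene Adh1c had a log2 fold change of -1.33 (SE 0.21), which passed adjusted over the list alone (limma adjusted p = 0.00156) and missed over all genes (limma adjusted p = 0.0612). Its log2 signal was 9.08 ± 0.03 (SD, n = 3) in control and 7.76 ± 0.35 (SD, n = 4) in ethanol placentas. The values of the others were -0.38 for Aldh9a1, -0.16 for Akr1a1, -0.13 for Adh5, 0.13 for Aldh7a1, 0.08 for the catalase gene Cat, 0.07 for Aldh3a2 and 0.01 for Aldh2, and the sign turned for Adh5 with median scaling and for Aldh2 with quantile or 75th percentile scaling. No list apart from the 7 named passed, with adjusted p-values of 0.0552 to 0.956. Within them some members passed over the list alone and missed over all genes. The antioxidant genes Gpx3 (-1.72, SE 0.32), Gpx1 (-0.69, SE 0.15) and the metallothionein gene Mt2A (-0.91, SE 0.20) were lower in a list with a camera adjusted p of 0.0658. Hsd11b2, whose enzyme inactivates corticosterone, had -1.75 (SE 0.30) and Hsd11b1, whose enzyme regenerates it, had -1.05 (SE 0.23), in a glucocorticoid list with a camera adjusted p of 0.826. Vegfa, an angiogenic growth factor gene, had 0.59 (SE 0.12), and Adm, encoding the vasodilator adrenomedullin, had -1.46 (SE 0.37), in the hypoxia list (camera adjusted p = 0.808). The placental growth factor gene Pgf had -2.74 (SE 0.78). The glucose transporter gene Slc2a3 had 1.09 (SE 0.25) and the amino acid transporter gene Slc7a8 had -0.74 (SE 0.17). The median, mean and test differed in sign for the angiogenesis, smooth muscle, glucocorticoid, apoptosis, macrophage and DNA methylation lists. Natural killer, T cell and neutrophil markers, with 4 measured genes, and X and Y genes, with 2, were not tested.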

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

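The bounds of the tests on second gene lists were written before those lists' values were seen. The demand that the quartiles of a list, not only its median, clear the bound was added after seeing the medians, and so was the look at albumin. A gap test within the 4 ethanol arrays passed its critical value for 10 of 138 measures, where about 1 in 20, or 6.9, is expected by chance.

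Decidual markers were lower in ethanol placentas, with scores between -1.19 and 0.098 against 0.548 to 0.917 in controls. Array scaling is argued against, since quantile normalization moved the median of the list by 0.039. Less maternal decidua in the ethanol samples stays open, since a second list of 18 measured uterine stroma genes had a median log2 fold change of -0.24 with quartiles of -0.53 and -0.01, between the bounds of -0.5 and -0.2. Within that list Hoxd10 (-1.90) and Hoxa9 (-1.59) were low while Pdgfra (-0.00) and Vim (-0.04) were not, and other placental cells may express several of its genes. An effect of ethanol on decidual expression is the biological explanation the design gives, and it was not tested apart from tissue content.

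Red cell genes were lower in ethanol placentas, with scores between -1.16 and 0.112 against 0.312 to 1.03. A second list of 18 measured red cell genes had a median of 0.061 with quartiles of -0.19 and 0.24. That median alone lies above the bound of -0.1 set against less blood left in the ethanol samples, but the lower quartile does not, and bright members such as Urod, between 3328 and 3552 in all arrays, may come from other placental cells and hide a change in blood, so this stays open. Without control replicate 3, the control with the highest score, the first list's median was -1.75 with quartiles of -1.89 and -0.19, so a larger blood share in one of the control samples is not enough for the median, while control replicate 1 at 0.956 keeps a larger share in a pair of controls open. An effect of ethanol on red cells in the placenta was not tested apart from blood content.

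Ethanol replicate 3 had a yolk sac score of 2.75, while the other ethanol arrays lay between -0.771 and -0.259. Albumin, abundant in liver, had a signal of 38.3 there against 32.1 to 91.2 elsewhere, which goes against fetal liver carried into the sample. Albumin is also on the yolk sac list behind this score, however, so it cannot tell liver from yolk sac membrane. It is a single gene as well. A list of 19 liver genes, 3 of which passed the filter on dim probe sets, lay at a median of -0.3 log2 units from the other arrays. Its quartiles were -1.47 and 0.315, and it leaves liver open, since the upper quartile is over the bound of 0.3. Yolk sac membrane carried into the sample stays open: a second yolk sac list of 16 measured genes lay 0.548 log2 units higher (median, quartiles 0.151 and 0.964), between the bounds of 0.3 and 1. In the first list Apoa1, Afp and Apob, which liver and yolk sac both make, had group log2 fold changes of 2.77, 1.95 and 2.32 that did not pass and were lowest without this array, at 1.59, 0.21 and 0.70 then, with an Afp signal of 22400 there against 96.3 to 260 in the other ethanol arrays. No biological explanation within the ethanol group was tested, since the labels give no difference between its samples.

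The other values far from the rest of the ethanol arrays were these. In ethanol replicate 3 the antioxidant score was -0.228 (others -0.0712 to -0.0623) and the nervous system score -0.0337 (others 0.101 to 0.112). In ethanol replicate 2 the oxidative phosphorylation score was -0.0244 (others -0.0402 to -0.0383), the Epb41l4a signal 1290 (others 1010 to 1040) and the Aldh2 signal 938 (others 727 to 754). In ethanol replicate 1 the Hyou1 signal was 795 (others 605 to 629) and the Ascl2 signal 22.1 (others 79.5 to 96.6). In ethanol replicate 4 the Laptm5 signal was 1180 (others 541 to 579) and the Lepr signal 581 (others 697 to 721).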

How the results depend on the processing

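The decidual score as a covariate was chosen after seeing the data, and all other alternatives before. The 24 named genes kept their direction in every alternative that measured them. The groups did not overlap for any of them, which the fill rule demanded. Leaving out an array or using 1 title set could therefore not turn their sign, and this is no separate support. No called list changed its camera direction except the ribosomal one, whose median became 0.043 with quantile normalization. The decidual list kept its call in 20 of 22 alternatives and the red cell list in 21 of 23, both losing it with an estimated correlation and with fry. The other called lists kept theirs in 13 to 18 of 23. The 29 lists without a call were called in 28 of 665 combinations of list and alternative, and changed camera direction in 47, none with a call. The 28 calls included the interferon and MHC class I list (camera adjusted p = 0.0378) and the ion transport list (camera adjusted p = 0.0378) with quantile normalization. They also included giant cell and junctional zone markers with median scaling (camera adjusted p = 0.0453). Each of these lists was called in several alternatives. Among them were the interferon list in title set 2 alone (camera adjusted p = 0.00307) and, without control replicate 2, ion transport (0.0102) and giant cell markers (0.00589). Leaving out control replicate 1, the lone control of title set 1, gives the same estimates as title set 2 alone, so these 2 alternatives are not independent. The causes were not tested. No detection calls were used, so how dim signals limit the results was tested by the filter, floor and pseudocount only. No paired analysis was possible because the replicate numbers only name samples.

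Against 11 changed probe sets, quantile normalization gave 2, median scaling 637, no filter 5, a 60% filter 0 (2923 with an unadjusted p under 0.05), no title set block 231, title set 1 alone 3, title set 2 alone 0 (1588 unadjusted), no variance trend 0 (3643 unadjusted), array weights 925, the decidual score as a covariate 7 (none of them among the 11), and leaving out 1 array between 0 and 1138. Against 1 changed gene, median scaling gave 642, no title set block 243, title set 2 alone 0, no variance trend 0, array weights 669, the mean of all probe sets 0, the probe set with the lowest p 155, a choice that favours small p-values by construction, the decidual covariate 2, and leaving out 1 array between 0 (without control replicate 1, 2 or 3, or ethanol replicate 3) and 857 (without ethanol replicate 4). Against 7 shifted lists, an estimated correlation gave 0, fry 0, the decidual covariate 2, and leaving out 1 array between 2 (without control replicate 3) and 11 (without control replicate 1).

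For genes the values below are log2 fold changes whose sign turned, and for lists they are medians where the camera direction turned. With the decidual covariate they were 0.090 for Adh5, -0.995 for Afp, -0.174 for Aldh2, -0.403 for Aldh7a1, -0.057 for Apob, 0.653 for Aqp1, -0.130 for Cat, 0.049 for Dcn (on the decidual list, so its change is fitted by construction), 0.022 for Pgf and 0.037 for Prl3a1, and for lists -0.051 for angiogenesis, -0.213 for cell cycle, -0.047 for DNA methylation, -0.062 for heat shock, 0.155 for hypoxia, -0.011 for imprinted genes, -0.040 for mesenchyme, -0.048 for nutrient transporters, -0.128 for smooth muscle and -0.775 for yolk sac. The decidual list has no value there, since its own score is fitted. With median scaling Adh5 was 0.0081 and DNA methylation 0.197. With quantile normalization Aldh2 was -0.011, glycogen trophoblast 0.079, hypoxia -0.024 and retinoid 0.023, and with 75th percentile scaling Aldh2 was -0.0035. In title set 2 alone Aldh2 was -0.095 and hypoxia -0.033. In title set 1 alone apoptosis was 0.160, cell cycle -0.0041, cholesterol 0.109, heat shock -0.097, immune response 0.324, macrophage 0.514, nervous system -0.194 and retinoid 0.089. The mean of all probe sets gave DNA methylation 0.032, no filter gave nervous system -0.232, no title set block gave retinoid -0.160 and the 60% filter gave Wnt and Notch 0.123. Leaving out 1 array gave -0.095 to 0.052 for Aldh2, -0.036 to 0.30 for Aldh7a1, -0.058 to 0.211 for Cat, 0.20 to 0.455 for angiogenesis, -0.042 to 0.106 for apoptosis, 0.0031 to 0.207 for cell cycle, -0.0019 to 0.112 for DNA methylation, -0.202 to -0.0099 for glycogen trophoblast, 0.029 to 0.155 for heat shock, -0.190 to 0.013 for hypoxia, -0.617 to 0.086 for immune response, -0.423 to 0.149 for macrophage, -0.301 to 0.052 for retinoid and -0.061 to 1.11 for yolk sac, whose lowest value came without ethanol replicate 3.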

Other observations

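Several further gene groups held members that passed adjusted over the list alone and missed over all genes, while their lists did not pass camera. Among matrix genes (camera adjusted p = 0.295) the gelatinase gene Mmp2 had a log2 fold change of -2.37 (SE 0.45) and the collagen gene Col5a2 had -1.64 (SE 0.38), while the laminin gene Lama4 had 0.69 (SE 0.13). The secreted Wnt modulator genes Sfrp4 and Dkk3 had -3.86 (SE 0.84) and -0.97 (SE 0.21) in a list with a camera adjusted p of 0.374. The lowest Sfrp4 signal, 19.2, lies under the 20th percentile of all signals, and its value lay between -4.60 (without ethanol replicate 1) and -3.23 (without ethanol replicate 2) with 1 array left out. Phospholamban, a muscle calcium regulator encoded by Pln, had -2.64 (SE 0.49) in the smooth muscle list (camera adjusted p = 0.394). It was -3.12 without control replicate 3 and -2.03 without control replicate 2. Most of that list went the other way, with 11 of 14 members higher, a median of 0.27 and a mean of -0.14. Adjusted over the list alone 1 member passed higher and 2 lower. In the macrophage list (camera adjusted p = 0.749), Cd14 had -1.56 (SE 0.33) and Laptm5 had -1.03 (SE 0.28). Of the imprinted genes (camera adjusted p = 0.374), Plagl1 had 0.85 (SE 0.21) and the growth factor receptor adaptor gene Grb10 had 0.66 (SE 0.17). The protease gene Htra1 had -1.44 (SE 0.38) and the insulin-like growth factor binding protein gene Igfbp6 had -1.43 (SE 0.39) in the IGF list (camera adjusted p = 0.621). The lipoprotein receptor gene Scarb1 had 0.91 (SE 0.17) in the steroid list (camera adjusted p = 0.105), and the glycogen phosphorylase gene Pygl had 0.78 (SE 0.15) in the glycogen trophoblast list (camera adjusted p = 0.808).

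In the ion transport list (camera adjusted p = 0.0658) no member passed over the list alone. The calcium channel gene Trpv6 had 1.80 (SE 0.57) and the calcium-binding protein gene S100g had 1.23 (SE 0.36), while the water channel gene Aqp1 had -3.26 (SE 1.06). With 1 array left out, Trpv6 lay between 1.08 (without control replicate 1) and 2.33 (without ethanol replicate 4), S100g between 0.95 and 1.65, and Aqp1 between -4.26 (without ethanol replicate 4) and -2.25 (without ethanol replicate 3). A hypothesis is that part of the differences between the groups follows the decidual content of the samples. With the decidual score as a covariate, chosen after seeing the data, Aqp1 became 0.653 and Pgf 0.022, both picked from the genes whose sign turned. Add3 stayed at -1.07 without passing (limma adjusted p = 0.527, over its alternatives 0.00726 to 0.527). Among the called lists the median went from -0.22 to -0.00 for endoplasmic reticulum stress, from 0.41 to 0.12 for endothelial markers and from -0.19 to -0.07 for ribosomal proteins, with adjusted p-values of 0.446, 0.702 and 0.446. The labyrinth median was 0.24 (adjusted p = 0.124). The prolactin list kept its call at -0.22 (camera adjusted p = 0.0367), and the red cell list kept it at a median of -2.59 (camera adjusted p = 1.55e-13). Both p-values rest on the preset correlation of 0.01. Without the covariate the estimated correlation of the red cell list was 0.417, and with that estimate it did not pass (camera adjusted p = 0.78). The small p-value is therefore no measure of the strength of this result. The score does not overlap between the groups, so the covariate may also remove an effect of ethanol, and it lowers the power. With it 795 probe sets had an unadjusted limma p under 0.05, against 931 expected by chance. The lost calls therefore do not decide on the hypothesis.

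Splits of the 7 arrays into 3 and 4 were counted, the real one included. There were 34 with the title set block, since 1 split cannot be told from the title sets, and 35 without it. Chance cannot be excluded at a share of 0.05 for any of the counts. As many as 11 probe sets were found in 2 of 34 splits, the real one included, and the highest other count was 807. At least 1 gene was found in 5 of 34 splits (highest other 633), and 7 or more lists in 14 of 34 (highest other 12). Without the block, 2 of 35 splits gave 231 or more probe sets (highest other 996) and 2 of 35 gave 243 or more genes (highest other 808). The highest other counts of probe sets and genes came from setting ethanol replicates 1, 2 and 3 against the controls with ethanol replicate 4. Counts so far above the real ones, 11 and 1 with the block and 231 and 243 without it, point to a structure of the samples. Whether it is a likeness of ethanol replicate 4 to the controls stays open. Across genes, which are not independent replicates, that array correlated at r = 0.973 with ethanol replicate 1, at 0.965 to 0.966 with the controls, and at 0.961 and 0.958 with ethanol replicates 3 and 2. Its scores lay among the controls for 4 called lists, such as prolactin hormones (0.179). They lay below the controls for red cell genes (-1.16) and decidual markers (0.098), and above them for labyrinth markers (0.119). It had the largest 3' to 5' difference for Actb (2.23) and Gapdh (0.86) and not for hexokinase (1.69, against 2.11 in control replicate 1), and the relation of RNA quality to the structure was not tested further.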
